A study of Homo sapiens with 10 samples.

How the data were processed

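The series held 10 tumours grown from MDA-MB-231 cells in NSG mice and collected after 21 days of treatment, with 1 RNA library per tumour. Total RNA was turned into strand-specific mRNA libraries and sequenced on the DNBSEQ platform, per the labels' protocols. HISAT, Bowtie2 and RSEM and the builds GRCh38.p12 and hg38 were named, without versions or roles, per the submitters' processing notes. The deposited file gave 1 column of expression per tumour for 16749 human gene symbols. It did not name the unit, and the values were read as FPKM (fragments scaled by transcript length and by library size): the deposited FPKM values had 2 decimals and differed in total between libraries, by 1.24 times, while the sum of value times transcript length, from GENCODE release 29, differed by 1.06 times. A scaling between libraries, a filter on genes and a step that sets mouse reads apart were not stated in the labels, so host RNA can have contributed to human gene values. Of the gene symbols, 38 were made of digits only.

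Tumours were grouped by the treatment in the labels: vehicle (3), OPG-Fc (2), palbociclib (2) and palbociclib with OPG-Fc (3). No library pair was identical. Depth was unknown, since the file held no counts. Relative depth was estimated from the steps between the lowest values, over 53 to 155 genes per library, and came to between -0.64 and 0.54 log2 of vehicle 3, with bootstrap SDs of up to 0.470, too wide to use. No interval that needs depth was therefore given.

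All tests were made in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1), with a trend of variance on mean expression. Genes with at least 1 FPKM in at least 2 libraries were tested, 11922 in all. The 10 tumours entered one model of 4 group means, with 6 residual degrees of freedom, so that groups of 2 shared the estimate of the spread with the others. The contrasts were each agent and the combination against vehicle, the combination against each agent, and the interaction (combination minus palbociclib, minus the difference of OPG-Fc and vehicle). Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. The test was checked on simulated data with 200 changed genes of 11922. It recovered 0% of changes of 1.5-fold in the 5 group comparisons. At 2-fold it recovered 50.5% in palbociclib against vehicle, 46% in OPG-Fc against vehicle, 71.5% in combination against vehicle, 47.5% in combination against palbociclib and 51% in combination against OPG-Fc. At 4-fold it recovered 97.5%, 98.5%, 99.5%, 99.5% and 99% in the same order. The simulated changes were made on the log2(FPKM + 1) scale in genes with a mean of at least 5, with noise independent between genes and libraries. They therefore do not exclude changes of that size among genes that did not pass. PAEP did not pass at 4.08 log2 in OPG-Fc against vehicle, nor BMP2 at 2.11 log2 in combination against palbociclib.

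Gene lists fixed before the data were examined, 27 in all, covered the cell cycle, the RANK pathway, immune, stress and metabolic programmes, quality signs and markers of other cell types. Of these, 25 had at least 2 tested genes; the erythroid markers and the mitochondrially encoded genes had 0. They were tested with camera, two-sided, with its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a contrast, and again with an estimated correlation. Of the 150 list tests 49 passed with the preset correlation, and 0 with the estimated one (lowest adjusted p = 0.205). The rotation test fry was a further alternative, which asks another question: whether a list changed at all, while camera compares it with the other genes. For each list, the members that passed over all genes and those that passed when adjusted over the list alone were counted.

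Genes were named by a rule written before the data were examined. For each of the 5 group comparisons it took the 10 largest rises and falls among genes that passed, with a mean of at least 2 in the higher group and no overlap of values, or the 5 genes with the smallest p in each direction, given as not passing, where none passed. The limits on mean and overlap were applied in both cases, and genes without a protein-coding name were not named. The genes given as not passing are therefore not those of smallest p over all genes. The rule also took up to 4 members with the smallest p of each list described, and a panel of drug target and proliferation genes. Symbols are those of the file. Coordinates came from GENCODE release 29 on GRCh38, found for 16111 symbols, and length and GC content for 16175.

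The alternatives planned before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5, quantile normalisation, scaling by a trimmed mean (TMM), rescaling to a common total, a robust prior, library quality weights, a model of only the groups compared, the replicate number as a block, the vehicle libraries 1 and 2 averaged (their names in the file share a stem, so both may come from 1 mouse), leaving out each library, the estimated correlation and fry. Removal of each library's trends on transcript length and GC content, the sign of the GC trend as a term, and a fit without the 2 libraries of lowest weight were added after the data were seen, as were a list of 12 MHC class II genes and comparisons of 5 against 5 tumours by palbociclib and by OPG-Fc. Values were read and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy and matplotlib 3.10.9.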

Results

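Gene expression was measured by RNA sequencing in 10 tumours grown under the skin of NSG mice from MDA-MB-231 cells, a human triple-negative breast cancer line. The mice had been treated for 21 days with vehicle (3 tumours), OPG-Fc (10 mg/kg, 3 times a week, 2 tumours), palbociclib (30 mg/kg per day, 2 tumours) or both agents (3 tumours), here called the combination. OPG-Fc is an osteoprotegerin fusion protein that binds the cytokine RANKL. Palbociclib inhibits the cell-cycle kinases CDK4 and CDK6. The control tumours were described in the labels both as vehicle-treated and as untreated. Values for 16749 human genes were given per tumour, read here as FPKM, and summed to between 507559 and 627799 per library. Between 834 and 1882 genes were listed at 0 in a library. Read depth was unknown, since the file held no counts. Libraries of the same group correlated across genes at 0.955 to 0.985, and libraries of different groups at 0.955 to 0.986. The first principal component held 33.1% of the variance and parted 5 libraries from the 5 others. The former, vehicle 1, both OPG-Fc libraries, palbociclib 2 and combination 2, had relatively higher values for GC-rich genes. Nothing in the labels stated whether the tumours of a group came from separate mice, so no p-value measured a spread beyond these tumours. Those of camera with its preset correlation compare a list with the other genes, under an assumed correlation of 0.01 between genes. They do not measure how far a list varied from tumour to tumour. The names of vehicle 1 and 2 in the file share a stem, so these tumours may come from 1 mouse. Values are means ± SD of FPKM, and log2 fold changes are differences of log2(FPKM + 1), which understate the change of genes with low values.

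The kinase genes CDK4 and CDK6 were expressed in all groups, and the gene of the RANKL receptor was near the floor. CDK4 averaged 69.7 ± 17.6 (n = 3) in vehicle, 95.5 ± 7.83 (n = 2) in OPG-Fc, 87.9 ± 0.757 (n = 2) in palbociclib and 66.4 ± 7.74 (n = 3) in combination tumours. CDK6 lay between 4.74 ± 1.12 (n = 2, OPG-Fc) and 7.69 ± 2.05 (n = 3, combination). CCND1, which encodes the cyclin D1 partner of both kinases, lay between 119 ± 34.1 (n = 2, OPG-Fc) and 201 ± 40.7 (n = 3, combination). RB1, whose product the kinases phosphorylate, lay between 14.4 ± 1.76 (n = 2, OPG-Fc) and 20.5 ± 1.62 (n = 3, vehicle). TNFRSF11A, which encodes the RANKL receptor RANK, lay between 0.157 ± 0.0351 (n = 3, combination) and 0.433 ± 0.120 (n = 3, vehicle), below the level required for testing. TNFRSF11B, which encodes osteoprotegerin itself, averaged 2.27 ± 0.389 (n = 3) in vehicle and 6.19 ± 4.79 (n = 3) in combination tumours. TNFSF11, which encodes RANKL, had no entry under that symbol in the deposited values, so it could not be analysed. None of the tested genes among these passed the test in any comparison.

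The comparison of combination with vehicle tumours asked what both agents did together, and DNA replication genes were lower throughout. UHRF1, which maintains DNA methylation during replication, fell from 28.3 ± 3.13 (n = 3) to 9.08 ± 0.333 (n = 3), a log2 fold change of -1.54 (SE 0.17, adjusted p = 0.0190). CDC6, which loads the replicative helicase at origins, fell from 15.4 ± 1.80 (n = 3) to 4.17 ± 1.08 (n = 3), a log2 fold change of -1.68 (SE 0.22, adjusted p = 0.0430). All 46 DNA replication and E2F target genes had negative log2 fold changes, with a median of -0.70. The list was lower than the other genes (camera, adjusted p = 1.40e-44), with adjusted p = 0.205 with an estimated correlation. Of its 46 genes 2 fell past the threshold over all genes, and 31 fell when adjusted over the list alone. Among the latter, CDT1, another origin licensing factor, averaged 16.2 ± 2.95 against 37.0 ± 2.24, and MCM3, a subunit of the helicase, 21.0 ± 4.21 against 47.0 ± 8.82 (n = 3 and 3).

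Mitosis and G2/M genes were also lower as a group in combination than in vehicle tumours, with negative values for 38 of 40 genes and a median of -0.32 (camera, adjusted p = 4.14e-12; adjusted p = 0.453 with an estimated correlation). None of the 40 passed over all genes. MKI67, which encodes the proliferation marker Ki-67, passed when adjusted over the list alone, at 16.8 ± 0.906 against 32.5 ± 8.94 (n = 3 and 3). Of the 18 tested genes of the CDK4/6-RB axis none passed over all genes, and 3 fell when adjusted over the list alone. They included the E-type cyclins CCNE2, at 0.763 ± 0.599 against 4.24 ± 1.44, and CCNE1, at 1.83 ± 1.13 against 6.09 ± 0.984 (n = 3 and 3). The last was the pocket protein gene RBL1, at 4.10 ± 1.63 against 10.2 ± 2.23. Cholesterol biosynthesis genes were lower as a group, with negative values for 23 of 25 and a median of -0.29 (camera, adjusted p = 9.28e-07; adjusted p = 0.504 with an estimated correlation). When adjusted over the list alone 2 fell, among them ACAT2, at 12.3 ± 2.18 against 23.6 ± 4.87 (n = 3 and 3). Over all genes 0 of the 25 passed. Genes of amino acid supply and the ATF4 stress response were lower in 16 of 23 cases, with a median of -0.26 (camera, adjusted p = 4.01e-04; adjusted p = 0.221 with an estimated correlation). Here PSAT1, an enzyme of serine synthesis, was the 1 gene that fell when adjusted over the list alone, at 12.5 ± 1.21 against 23.0 ± 6.67. NF-kB target genes were higher in 26 of 29 cases, with a median of 0.51 (camera, adjusted p = 6.67e-08; adjusted p = 0.515 with an estimated correlation). The median was 0.26 without vehicle 3 and 0.33 without combination 1. None of these 29 passed either adjustment. The cytokine genes CSF2, at 23.0 ± 17.2 against 8.09 ± 4.87, and CXCL8, at 103 ± 51.9 against 40.9 ± 41.4, varied widely between tumours.

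In limma, with Benjamini-Hochberg adjustment over 11922 genes, 2 genes passed in this comparison, UHRF1 (GRCh38 chromosome 19, 4903080 to 4962154) and CDC6 (chromosome 17, 40287633 to 40304657). An unadjusted p under 0.05 was found for 629, where chance gives 596.1. No gene passed without any 1 of the 3 vehicle libraries, without combination 3, or with the vehicle libraries 1 and 2 averaged. Nor did any pass with no filter on low values, after rescaling to a common total, or with only these groups in the fit. The replicate number as a block also left 0. In contrast, 6 passed without combination 2 and 235 with libraries weighted by quality.

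**Figure D1:**
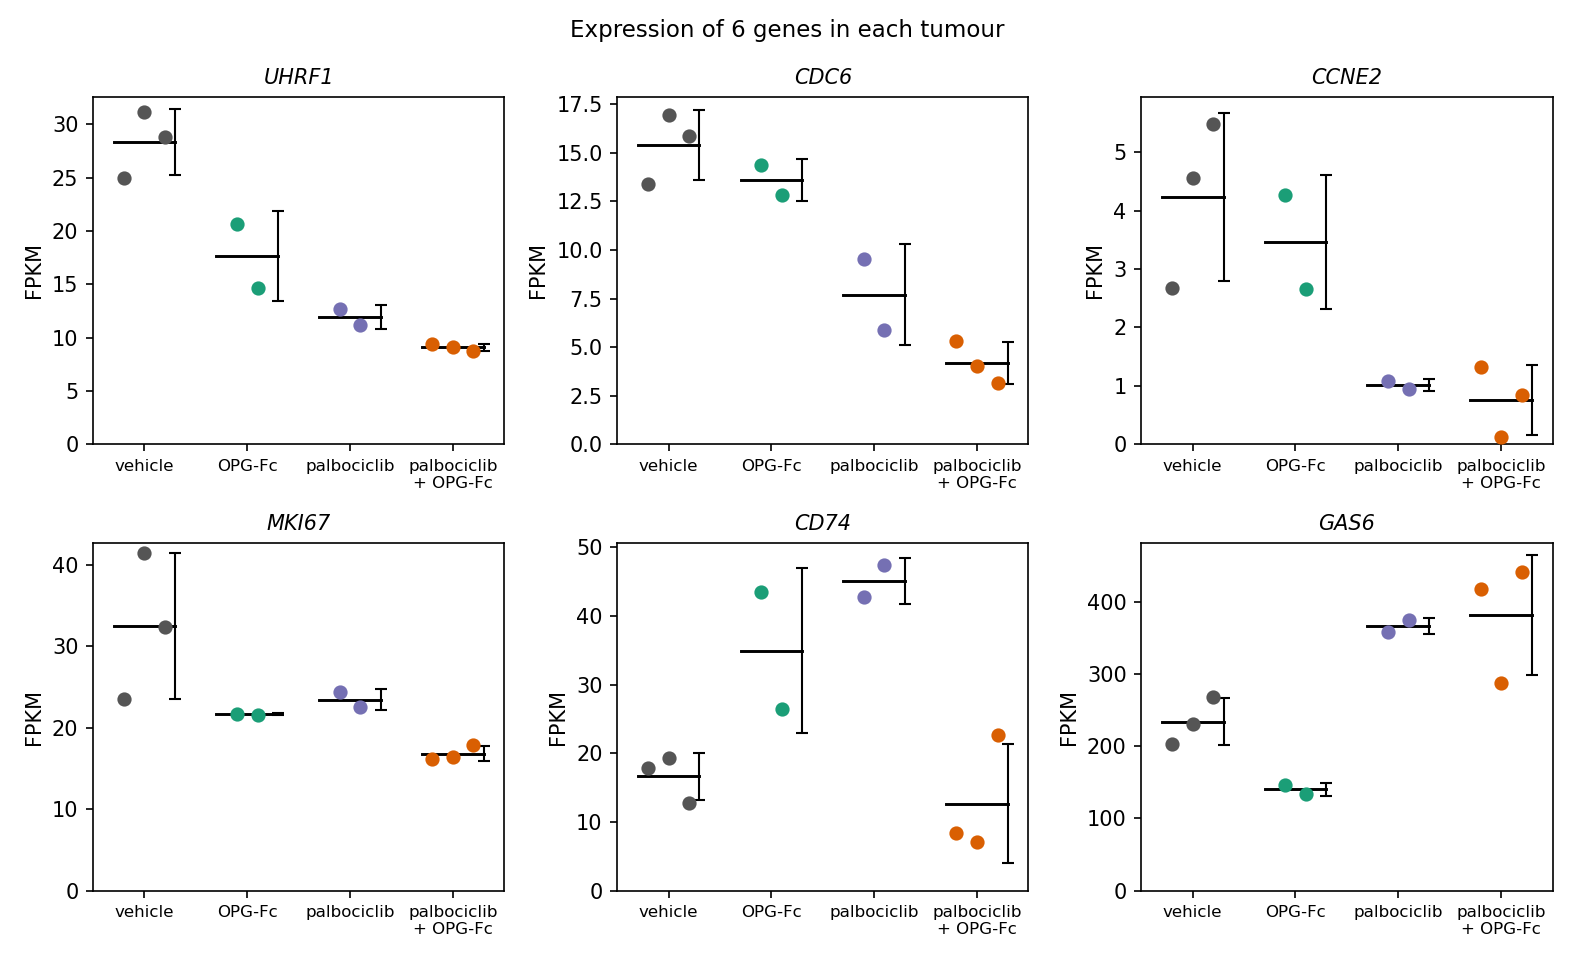
FPKM of 6 genes in each tumour (points), with the group mean (horizontal line) and 1 SD (bar), for vehicle (n = 3), OPG-Fc (n = 2), palbociclib (n = 2) and palbociclib with OPG-Fc (n = 3). UHRF1 averaged 28.3 in vehicle and 9.08 in combination tumours, and CDC6 15.4 and 4.17.

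The comparison of palbociclib with vehicle tumours asked what the CDK4/6 inhibitor did alone. DNA replication and E2F target genes were lower as a group, with negative log2 fold changes for 41 of 46 genes and a median of -0.34 (camera, adjusted p = 5.39e-08; adjusted p = 0.544 with an estimated correlation). The median was -0.23 without vehicle 3 and -0.52 without palbociclib 1. None of the 46 passed over all genes, and 4 fell when adjusted over the list alone. These included UHRF1, at 11.9 ± 1.10 against 28.3 ± 3.13, and CCNE2, at 1.01 ± 0.0990 against 4.24 ± 1.44. The others were CDC6, at 7.71 ± 2.60 against 15.4 ± 1.80, and the replication factor MCM10, at 2.17 ± 0.474 against 5.49 ± 1.38 (n = 2 and 3). Genes of MHC class I antigen presentation were higher as a group, with positive values for 13 of 19 and a median of 0.47 (camera, adjusted p = 8.21e-05; adjusted p = 0.244 with an estimated correlation). Over all genes 0 passed, and 7 rose when adjusted over the list alone. Among these 7 was HLA-C, which encodes a class I heavy chain, at 691 ± 80.6 against 408 ± 52.6. The immunoproteasome gene PSMB9 averaged 21.8 ± 3.41 against 10.1 ± 2.76 (n = 2 and 3).

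Mesenchymal transition genes were lower in palbociclib than in vehicle tumours in 20 of 22 cases, with a median of -0.55 (camera, adjusted p = 1.10e-04; adjusted p = 0.244 with an estimated correlation). No member passed over all genes or adjusted over the list alone. CTGF, a secreted matricellular protein gene, averaged 82.2 ± 16.0 against 192 ± 62.6, and TNC, which encodes the matrix protein tenascin C, 8.97 ± 4.80 against 31.2 ± 10.9 (n = 2 and 3). Endothelial markers were lower in the same comparison in 5 of 7 cases, with a median of -0.53 (camera, adjusted p = 0.0311; adjusted p = 0.244 with an estimated correlation), a call that ended without palbociclib 1 (adjusted p = 0.131). The mean log2 value of fibroblast and stromal markers was 1.78 ± 0.317 against 2.34 ± 0.808, a list not called (adjusted p = 0.185). Skeletal muscle markers were lower in 13 of 13 cases (camera, adjusted p = 0.0212; adjusted p = 0.747 with an estimated correlation). That call ended without vehicle 1 (adjusted p = 0.0670), vehicle 3 (adjusted p = 0.533) or palbociclib 1 (adjusted p = 0.347). Ribosomal protein genes were higher in 33 of 33 cases, with a median of 0.35 (camera, adjusted p = 1.90e-09; adjusted p = 0.544 with an estimated correlation). So were oxidative phosphorylation genes in 23 of 32, with a median of 0.19 (camera, adjusted p = 0.00197; adjusted p = 0.544 with an estimated correlation). No gene of either list passed either adjustment, and the call on ribosomal proteins ended under quantile normalisation (adjusted p = 0.0987). KRT14, which encodes the skin keratin 14, was listed at 172 in palbociclib 2 and 0.490 in palbociclib 1.

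No gene passed in limma in the comparison of palbociclib with vehicle (smallest adjusted p = 0.427), and 1228 had an unadjusted p under 0.05. The 10 genes named by the rule, those of smallest p among genes without overlap of values, 5 in each direction, did not pass. They included MFAP2, a microfibril protein gene, at 107 ± 42.0 against 30.9 ± 1.15, and AKAP12, a scaffold of protein kinase A, at 2.25 ± 0.0990 against 9.88 ± 1.95. Another was HMGA2, an architectural chromatin protein gene, at 24.99 ± 5.20 against 46.9 ± 3.16 (n = 2 and 3). The chorionic gonadotropin genes CGB8 and CGB2 were also among them, but near-identical copies share their reads, so their values were uncertain. The count became 43 with libraries weighted by quality (14 higher, 29 lower), 39 with only these groups in the fit (15 higher, 24 lower) and 1 without palbociclib 2.

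The comparison of OPG-Fc with vehicle tumours asked what OPG-Fc did alone. Ribosomal protein genes were higher in OPG-Fc tumours in 33 of 33 cases, with a median log2 fold change of 0.53 (camera, adjusted p = 1.77e-28; adjusted p = 0.459 with an estimated correlation). RPS3 averaged 2450 ± 679 against 1445 ± 369 and RPL8 2415 ± 113 against 1600 ± 291 (n = 2 and 3). No gene of this list passed over all genes or adjusted over the list alone. Both OPG-Fc libraries belonged to the 5 with a positive trend on GC content, and against vehicle 1, the only vehicle library among these 5, the median was 0.27. Oxidative phosphorylation genes were higher in 27 of 32 cases, with a median of 0.23 (camera, adjusted p = 2.80e-08; adjusted p = 0.459 with an estimated correlation). Against vehicle 1 their median was 0.10. Skeletal muscle markers were also higher, in 12 of 13 cases (camera, adjusted p = 1.71e-04; adjusted p = 0.698 with an estimated correlation), with a mean log2 value of 4.05 in OPG-Fc 1 and 1.69 in OPG-Fc 2. Their call ended without vehicle 2 (adjusted p = 0.116) or OPG-Fc 1 (adjusted p = 0.689). None of the 32 oxidative phosphorylation genes passed either adjustment. NDUFA2, a complex I subunit gene, averaged 59.0 ± 18.6 against 36.4 ± 1.91 (n = 2 and 3).

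No call was made in this comparison for DNA replication and E2F target genes, which had a median of -0.17 (camera, adjusted p = 0.133), or for mitosis and G2/M genes, with a median of -0.20 (camera, adjusted p = 0.118). No gene passed in limma (smallest adjusted p = 0.775), and 711 had an unadjusted p under 0.05. Among the 10 genes named by the same rule, which did not pass, PODXL, a cell surface sialomucin gene, averaged 95.3 ± 8.82 against 210 ± 37.7. SLC7A5, which encodes an amino acid transporter, averaged 59.6 ± 4.89 against 122 ± 15.9, and KMT2D, a histone methyltransferase gene, 3.17 ± 0.127 against 7.19 ± 1.54 (n = 2 and 3). PAEP, which encodes the secreted protein glycodelin, was listed at 14.5 and 139 in the OPG-Fc tumours and at 6.52, 1.46 and 0.140 in the vehicle tumours. Without OPG-Fc 2 the count became 2.

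The comparison of combination with palbociclib tumours asked what OPG-Fc added to palbociclib, the question closest to the title of the series. DNA replication and E2F target genes were lower as a group in combination tumours, with negative log2 fold changes for 43 of 46 genes and a median of -0.32 (camera, adjusted p = 4.25e-11; adjusted p = 0.456 with an estimated correlation). The median was -0.19 without palbociclib 1 and -0.49 without palbociclib 2, and the mean log2 value of the list was 3.29 in both palbociclib 2 and combination 1. Not 1 of these passed over all genes or adjusted over the list alone. TK1, which encodes thymidine kinase, averaged 77.8 ± 3.60 against 112 ± 1.17, and CDC45, a helicase cofactor gene, 8.94 ± 1.51 against 14.3 ± 0.163 (n = 3 and 2). Mitosis and G2/M genes were lower in 37 of 40 cases, with a median of -0.35 (camera, adjusted p = 3.79e-10; adjusted p = 0.456 with an estimated correlation). Over all genes 0 passed. AURKB, which encodes the mitotic kinase aurora B, was the 1 gene that fell when adjusted over the list alone, at 57.0 ± 7.58 against 94.6 ± 13.1 (n = 3 and 2).

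MHC class I genes were lower in combination than in palbociclib tumours in 14 of 19 cases, with a median of -0.20 (camera, adjusted p = 0.00103; adjusted p = 0.456 with an estimated correlation). None passed over all genes, and 3 fell when adjusted over the list alone. Among them was HLA-C, at 412 ± 38.4 against 691 ± 80.6 (n = 3 and 2). Mesenchymal transition genes were higher in 20 of 22 cases, with a median of 0.38 (camera, adjusted p = 4.88e-04; adjusted p = 0.456 with an estimated correlation). With them, fibroblast and stromal markers had a mean log2 value of 2.29 ± 0.469 against 1.78 ± 0.317 (not called, adjusted p = 0.113), and skeletal muscle markers were higher in 13 of 13 cases (camera, adjusted p = 0.00589; adjusted p = 0.641 with an estimated correlation). The muscle call ended without palbociclib 1 (adjusted p = 0.380) or combination 3 (adjusted p = 0.415). NF-kB target genes were higher in 27 of 29, with a median of 0.58 (camera, adjusted p = 1.01e-04; adjusted p = 0.638 with an estimated correlation). No mesenchymal or NF-kB gene passed either adjustment. THBS1, which encodes thrombospondin 1, averaged 22.3 ± 5.46 against 12.3 ± 2.98. Oxidative phosphorylation genes were lower in 26 of 32 cases, with a median of -0.24 (camera, adjusted p = 1.01e-04; adjusted p = 0.456 with an estimated correlation), none passing either adjustment. The MHC class I median was -0.32 without palbociclib 1, and the call ended without palbociclib 2 (adjusted p = 0.0717). The mesenchymal call ended without palbociclib 1 (adjusted p = 0.0558). The NF-kB call ended without palbociclib 1 or without combination 2 (camera, adjusted p = 0.0749), and its median was 0.36 without combination 1. The mean log2 value of the NF-kB list varied widely within both groups, at 4.47 ± 0.460 in combination and 3.90 ± 0.503 in palbociclib tumours (n = 3 and 2).

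No gene passed in limma in the comparison of combination with palbociclib (smallest adjusted p = 0.639), and 763 had an unadjusted p under 0.05. Among the 10 genes named by the same rule, which did not pass, HMGA2 averaged 48.6 ± 5.60 against 24.99 ± 5.20 and MGLL, which encodes monoglyceride lipase, 49.5 ± 16.2 against 18.0 ± 1.99. SERPINF1, which encodes an inhibitor of vessel growth, averaged 38.5 ± 12.9 against 122 ± 30.0, and CD74, the MHC class II invariant chain gene, 12.7 ± 8.62 against 45.1 ± 3.36 (n = 3 and 2). The count became 1 without palbociclib 2, without combination 2 or without combination 3.

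**Figure D2:**
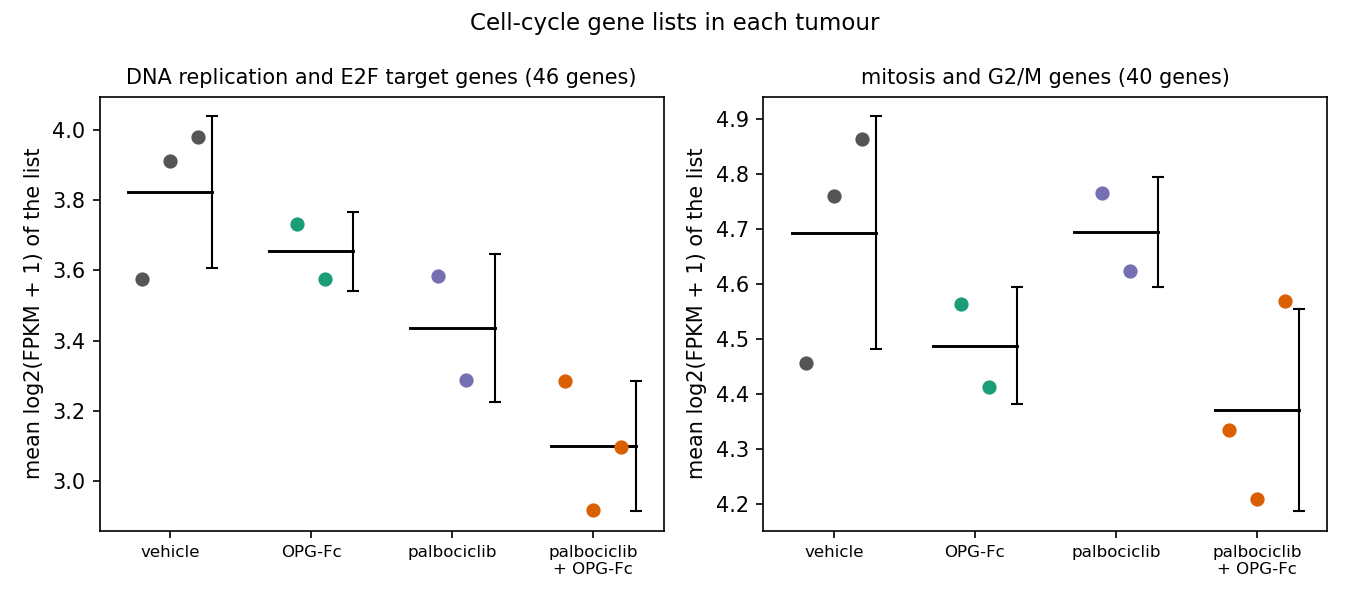
Mean log2(FPKM + 1) of 46 DNA replication and E2F target genes (left) and of 40 mitosis and G2/M genes (right) in each tumour (points), with the group mean (horizontal line) and 1 SD (bar). The 3 combination tumours lay between 2.92 and 3.29 on the left panel and the 3 vehicle tumours between 3.58 and 3.98.

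The comparison of combination with OPG-Fc tumours asked what palbociclib added to OPG-Fc. DNA replication and E2F target genes were lower as a group in combination tumours, with negative log2 fold changes for 42 of 46 genes and a median of -0.57 (camera, adjusted p = 1.50e-22; adjusted p = 0.478 with an estimated correlation). None passed over all genes and 21 fell when adjusted over the list alone. Among these 21, CDC6 averaged 4.17 ± 1.08 against 13.6 ± 1.07 and CDT1 16.2 ± 2.95 against 37.9 ± 5.54. The DNA polymerase subunit gene POLE2 averaged 4.0 ± 0.819 against 10.2 ± 0.0141 (n = 3 and 2). Type I interferon-stimulated genes were higher in 33 of 36 cases, with a median of 0.53 (camera, adjusted p = 5.03e-05; adjusted p = 0.623 with an estimated correlation), none passing either adjustment. The mean log2 value of this list was 3.47 and 3.37 in combination 1 and 3 but 2.55 in combination 2, below OPG-Fc 2 at 2.70. Its median was 0.33 without combination 1 and 0.91 without combination 2. IFI6 averaged 22.0 ± 9.15 against 10.8 ± 0.120 and SAMD9, an antiviral factor gene, 7.83 ± 2.94 against 3.44 ± 0.0636 (n = 3 and 2).

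Cholesterol biosynthesis genes were lower in combination than in OPG-Fc tumours in 21 of 25 cases, with a median of -0.28 (camera, adjusted p = 1.23e-06; adjusted p = 0.478 with an estimated correlation). Over all genes 0 passed. ACAT2, at 12.3 ± 2.18 against 24.8 ± 2.04, and FDFT1, which encodes squalene synthase, at 61.3 ± 15.8 against 109 ± 4.41, were the 2 that fell when adjusted over the list alone. Ribosomal protein genes were lower in 33 of 33 cases, with a median of -0.41 (camera, adjusted p = 7.16e-14; adjusted p = 0.478 with an estimated correlation). Oxidative phosphorylation genes were lower in 29 of 32, with a median of -0.24 (camera, adjusted p = 6.61e-07; adjusted p = 0.478 with an estimated correlation). Skeletal muscle markers were lower in 12 of 13 cases (camera, adjusted p = 0.00146; adjusted p = 0.671 with an estimated correlation), a call that ended without OPG-Fc 1 (adjusted p = 0.974). No ribosomal or oxidative phosphorylation gene passed either adjustment. The median deviation of ribosomal protein genes from their means over all libraries was 0.17 in OPG-Fc 1 and 0.46 in OPG-Fc 2. It was -0.30, -0.14 and 0.07 in combination 1, 2 and 3. No gene passed in limma in this comparison (smallest adjusted p = 0.177), and 1215 had an unadjusted p under 0.05. Among the 10 genes named by the same rule, which did not pass, GAS6, which encodes a ligand of TAM receptors, averaged 382 ± 83.0 against 140 ± 8.75 and PODXL 204 ± 34.8 against 95.3 ± 8.82. UNG, a uracil-DNA glycosylase gene, averaged 12.9 ± 4.11 against 31.5 ± 3.995, and CDC25A, which encodes a phosphatase that activates cyclin-dependent kinases, 1.20 ± 0.229 against 3.95 ± 0.134 (n = 3 and 2). The count became 356 without combination 2 (270 higher, 86 lower) and 876 with libraries weighted by quality (653 higher, 223 lower). Combination 2, the library of lowest weight, was the only combination library with a positive GC trend. Without it, group and the sign of that trend ran together, since both OPG-Fc libraries had a positive one. A split of the 10 tumours by that sign called 1889 genes (below), so these counts cannot be told apart from it.

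The interaction of both agents asked whether the difference between OPG-Fc-treated and other tumours changed when palbociclib was given. Ribosomal protein genes were higher with each agent alone than with vehicle, and their interaction was negative for 33 of 33 genes, with a median of -0.79 (camera, adjusted p = 2.33e-21; adjusted p = 0.436 with an estimated correlation). Both OPG-Fc libraries had a positive trend on GC content, as had 1 library of each other group. Against vehicle 1 alone the OPG-Fc median of 0.53 was 0.27. Trends on transcript length (Spearman) were negative in both OPG-Fc (-0.15, -0.26) and both palbociclib libraries (-0.10, -0.25). They were positive in vehicle 2 and 3 (0.38, 0.31) and combination 1 (0.22). In vehicle 1, combination 2 and combination 3 they were -0.13, -0.04 and 0.02. Removal of both trends kept the ribosomal call, but takes out only a shift shared by genes of similar length and GC content. Their part in the interaction stays open. Oxidative phosphorylation genes had negative values in 30 of 32 cases, with a median of -0.44 (camera, adjusted p = 4.82e-09; adjusted p = 0.436 with an estimated correlation). Mesenchymal transition genes had positive values in 19 of 22, with a median of 0.68 (camera, adjusted p = 0.00268; adjusted p = 0.436 with an estimated correlation). Without combination 2 their median was 0.41. Fibroblast and stromal markers moved with the mesenchymal genes, positive in 9 of 9 cases, with a median of 1.21 (camera, adjusted p = 0.0225; adjusted p = 0.812 with an estimated correlation). The fibroblast call ended without vehicle 2 (adjusted p = 0.0545), OPG-Fc 2 (adjusted p = 0.0566), palbociclib 1 (adjusted p = 0.147), combination 1 (adjusted p = 0.0568) or combination 3 (adjusted p = 0.0770). Over all genes none of the genes of these lists passed, while 18 ribosomal protein genes, 0 oxidative phosphorylation genes and 1 mesenchymal gene passed when adjusted over the list alone. DNA replication and E2F target genes had a median of -0.22 (camera, adjusted p = 0.00283; adjusted p = 0.812 with an estimated correlation), which turned to 0.06 after rescaling to a common total, as the median of all genes moved from 0.10 to 0.37.

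No gene passed in limma for the interaction (smallest adjusted p = 0.467), and 1269 had an unadjusted p under 0.05. Among genes already named by the comparisons above, PODXL had an interaction of 1.61 on the log2 scale (SE 0.28), GALNT5, a glycosyltransferase gene, 2.36 (SE 0.45) and CD74 -2.93 (SE 0.56). The E2F call ended without vehicle 1 (adjusted p = 0.170), OPG-Fc 1 (adjusted p = 0.0963) or palbociclib 1 (adjusted p = 0.147). Its median was -0.37 without palbociclib 2 and -0.06 without combination 2. The count became 3 without combination 2, 1 without combination 3, and 1030 with libraries weighted by quality (786 positive, 244 negative). The weights were lowest for combination 2 and vehicle 1, the only libraries of their groups with a positive GC trend. The split of the libraries by that trend can therefore enter the weighted count.

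**Figure D3:**
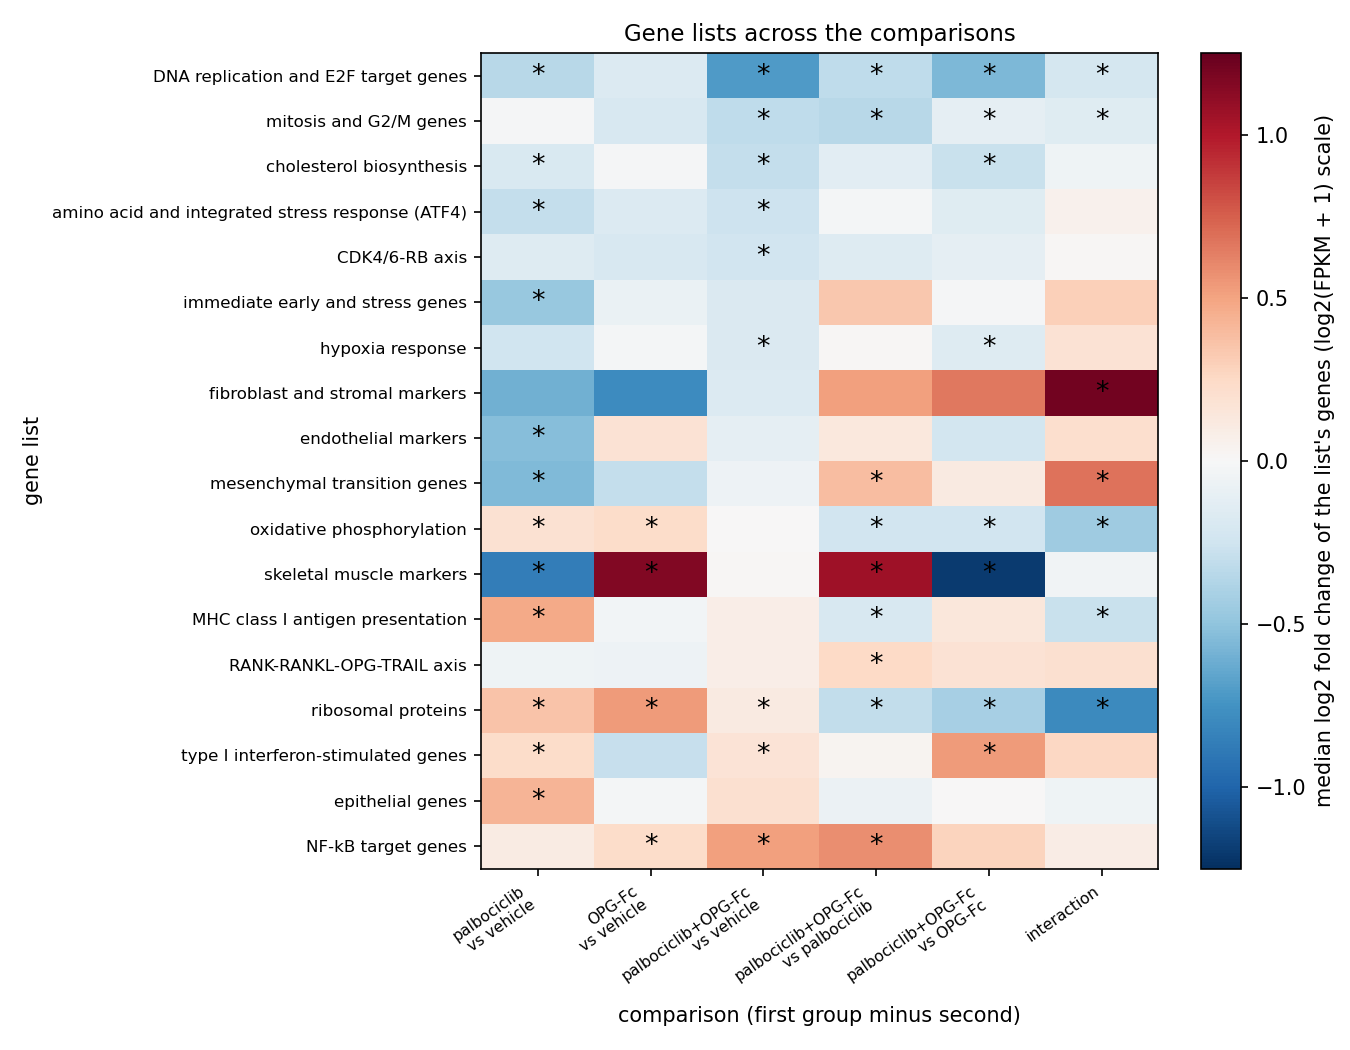
Median log2 fold change of the tested genes of each list (rows) in each comparison (columns), for the lists called in at least 1 comparison, with an asterisk where camera with its preset correlation gave an adjusted p under 0.05. DNA replication and E2F target genes had medians of -0.34, -0.17 and -0.70 in palbociclib, OPG-Fc and combination against vehicle, and under rescaling to a common total their interaction median turned from -0.22 to 0.06 as that of all genes moved from 0.10 to 0.37.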

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

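The tests of dilution by host RNA, of mouse macrophage reads and of libraries of one sign of the GC trend were chosen only after the results were seen. The results below drew attention because camera, with its preset correlation, called the interaction term of 7 lists. The values are adjusted p over 25 lists. They were 2.33e-21 for ribosomal proteins (negative for 33 of 33 genes, median -0.79 log2), 4.82e-09 for oxidative phosphorylation (30 of 32 negative, median -0.44), 0.00268 for mesenchymal transition genes (19 of 22 positive, median 0.68), 0.00283 for DNA replication and E2F target genes (33 of 46 negative, median -0.22), 0.0157 for mitosis and G2/M genes (25 of 40 negative, median -0.15), 0.0225 for fibroblast and stromal markers (9 of 9 positive, median 1.21) and 0.0262 for MHC class I genes (14 of 19 negative, median -0.27). With an estimated correlation the adjusted p was 0.436 for the first 3 and 0.812 for the others. After rescaling to a common total the medians of the E2F, mitosis and MHC class I lists turned to 0.06, 0.15 and 0.02, as the median of all genes moved from 0.10 to 0.37. Of 24 alternatives, 9 ended the MHC class I call, among them leaving out vehicle 3 (0.0518), OPG-Fc 2 (0.146) or palbociclib 2 (0.165), and 8 the fibroblast call, among them leaving out vehicle 2 (0.0545), OPG-Fc 2 (0.0566), palbociclib 1 (0.147), combination 1 (0.0568) or combination 3 (0.0770). The mitosis call was ended by 9, among them leaving out vehicle 1 (0.359), OPG-Fc 1 (0.172), palbociclib 1 (0.0787) or combination 1 (0.0568), and the E2F call by 5, among them leaving out vehicle 1 (0.170), OPG-Fc 1 (0.0963) or palbociclib 1 (0.147). The mesenchymal call was ended by 1, the fit without both low-weight libraries (0.0591).

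DNA replication and E2F target genes were lower in combination than in vehicle tumours, with a median log2 fold change of -0.70. Trends on gene length and GC content were not the whole of it, since after their removal the median was -0.71, and among libraries with a negative GC trend, 2 against 2, it was -0.77 (quartiles over genes -0.99 and -0.40), while the positive side held only 1 library of each group. Combination 2, the library of lowest weight, did not carry it alone (median without it -0.59), and all genes, which dilution by host RNA would lower too, had a median of 0.00912, although scaling by library size could hide an even dilution. Of the 10 splits of the 6 tumours 1, the real one, gave as large a list median (0.705; highest other 0.542), and 1, the real one, as many genes (2; highest other 0), but 10 splits are too few to say whether chance is excluded. A candidate explanation that remains is lower cell-cycle activity under palbociclib with OPG-Fc, a hypothesis found and tested on the same tumours.

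Ribosomal protein genes were higher in OPG-Fc than in vehicle tumours, with a median of 0.53. Removal of the length and GC trends left 0.51, but takes out only a shift shared by genes of similar length and GC content. It cannot exclude a library property that acts on this list. Deviations of all genes correlated with transcript length (Spearman) at -0.13, 0.38 and 0.31 in vehicle 1, 2 and 3. In OPG-Fc 1 and 2 they did so at -0.15 and -0.26. Median ribosomal deviations were 0.055, -0.37, -0.33, 0.17 and 0.46 in the same order. Scaling by a trimmed mean, which discounts a few genes that take most of the FPKM, gave 0.65, so such genes do not account for it. For oxidative phosphorylation genes the removal of trends gave 0.24 (from 0.23). Whether the split of the libraries by the sign of their GC trend could be the source cannot be told apart from OPG-Fc, since both OPG-Fc libraries lie on 1 side with 1 of 3 vehicle libraries, and against that library the median was 0.27 (quartiles 0.19 and 0.34). An effect of OPG-Fc stays open, as does a property shared by these libraries.

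CD74 averaged 16.6 ± 3.44 (n = 3) in vehicle, 34.97 ± 12.035 (n = 2) in OPG-Fc, 45.1 ± 3.36 (n = 2) in palbociclib and 12.7 ± 8.62 (n = 3) in combination tumours, an interaction of -2.93 log2 (SE 0.56, adjusted p = 0.467), which did not pass. It was -2.82 (SE 0.54) after removal of the length and GC trends. That removal takes out only a shift shared by genes of similar length and GC content, so it cannot decide the cause of a change in 1 gene. With the sign of the GC trend as a term the interaction was -3.11 (SE 0.64), which argues against that split of the libraries as the whole cause. Reads from mouse macrophages might contribute: the 5 tested macrophage and myeloid markers had a median interaction of -0.0543 but went both ways, from -0.81 for LYZ to 0.54 for CD68, so this cannot be told apart. The most abundant of these markers, CD68, averaged 89.6 in vehicle and 39.3 in palbociclib tumours. An effect of the treatments on CD74 stays open.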

How the results depend on the processing

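The removal of length and GC trends, the sign of the GC trend as a term and the fit without combination 2 and vehicle 1, the libraries of lowest weight, were tests chosen only after the results were seen. Over all alternatives, 89 of the counts of genes stayed within 1.5 times and 36 moved, while for the lists 870 stayed, 242 were no longer called and 3 turned in the direction camera gave. No count test was run, since the file held no counts, permutation per gene was not run, since 10 splits of 3 against 3 tumours cannot pass the threshold, and the interaction cannot be fitted with only 2 groups. Leaving out 1 tumour of a pair left a lone sample, assumed to vary like the other groups. In the text below the cause was not tested, except that fits with only 2 groups or without libraries used fewer samples and the fit without a filter tested more genes.

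For palbociclib against vehicle, with 0 genes and 1228 at an unadjusted p under 0.05 in limma, quality weights gave 43, only the 2 groups 39 and the fit without both low-weight libraries 2; leaving out 1 library gave 0 to 1. For OPG-Fc against vehicle it gave 0 to 2. For combination against vehicle, with 2, quality weights gave 235, quantile normalisation 10, the removal of trends 15, the GC sign as a term 15, the fit without both low-weight libraries 15, and 0 genes passed with no filter, with rescaling to a common total, with only the 2 groups and with vehicle 1 and 2 averaged; leaving out 1 library gave 0 to 6. For combination against palbociclib the fit without both gave 1 and leaving out 1 library 0 to 1. For combination against OPG-Fc quantile normalisation gave 1, quality weights 876, the removal of trends 11, the GC sign as a term 1, the fit without both 998 (820 higher, 178 lower) and leaving out 1 library 0 to 356. For the interaction quality weights gave 1030, the fit without both 875 (778 positive, 97 negative) and leaving out 1 library 0 to 3. Both low-weight libraries were the only ones of their groups with a positive GC trend. Without them vehicle and combination libraries all had a negative trend and both OPG-Fc libraries a positive one. The large counts against OPG-Fc and for the interaction therefore cannot be told apart from that split of the libraries.

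Replicate numbers did not pair the tumours: deviations of same-numbered libraries correlated at -0.28 to 0.35, over 0.1 in 5 of 13 pairs, and 5 of 10 libraries correlated best with their own number. With the number as a block 0 genes passed in combination against vehicle, and no other count moved.

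For the lists, adjusted p with an estimated correlation and with fry were, for E2F target genes, 0.544 and 0.267 (palbociclib against vehicle), 0.205 and 0.0695 (combination against vehicle), 0.456 and 0.407 (against palbociclib), 0.478 and 0.372 (against OPG-Fc) and 0.812 and 0.726 (interaction). For mitosis genes they were 0.453 and 0.448, 0.456 and 0.407, 0.671 and 0.635, and 0.812 and 0.726 in the last 4 of these, and for ribosomal proteins in OPG-Fc against vehicle 0.459 and 0.555. Under the 20 or 21 other alternatives all the E2F calls between groups and the ribosomal call were kept, as were the mitosis calls against vehicle and palbociclib. The mitosis call against OPG-Fc spanned 1.20e-04 to 0.0637 on leaving out 1 library, and its median turned from -0.11 to 0.02 after rescaling to a common total, a shift that all genes shared (below). In the interaction, E2F gave 0.213 with quality weights, 0.186 without both low-weight libraries and 4.70e-06 to 0.170 on leaving out 1 library. Mitosis gave 0.0782 with quantile normalisation, 0.0597 with rescaling, 0.0502 with quality weights, 0.0618 with vehicle 1 and 2 averaged, 0.311 without both and 8.63e-04 to 0.359 on leaving out 1. Hypoxia genes turned in combination against vehicle with quality weights (0.730) and against OPG-Fc without OPG-Fc 2 (1.02e-06 to 0.753 over the libraries left out), and NF-kB target genes in OPG-Fc against vehicle with the GC sign as a term (0.840). The log2 fold change of CDK4 in combination against vehicle, not past the threshold, turned from -0.05 to 0.0569 with quality weights and 0.19 without both low-weight libraries, and spanned -0.19 to 0.15 on leaving out 1 library. For the genes named, 1600 of the values stayed on the same side of the threshold, 18 lost it and 101 passed it.

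Rescaling to a common total moved the median log2 fold change of all genes from -0.02 to -0.17 (palbociclib against vehicle), -0.10 to -0.26 (OPG-Fc against vehicle), 0.02 to 0.13 (combination against palbociclib), 0.10 to 0.23 (against OPG-Fc) and 0.10 to 0.37 (interaction). Unknown depth limits what can be said of genes with low values.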

Other observations

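The tests of the MHC class II genes, of 5 against 5 tumours and of the split by GC trend were chosen only after the results were seen.

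Further lists were called by camera with its preset correlation. In palbociclib against vehicle, type I interferon-stimulated genes were higher (26 of 36, adjusted p = 0.0128; adjusted p = 0.747 with an estimated correlation; IFI6 26.0 ± 1.03 against 11.3 ± 2.46), as were epithelial genes (12 of 15, adjusted p = 0.0401; adjusted p = 0.244 with an estimated correlation). The mean log2 value of the epithelial list was 4.33 in palbociclib 2 alone, against 3.34 in palbociclib 1 and 3.24 to 3.45 in vehicle. Keratinocyte and skin markers went with it (4.21 in palbociclib 2, 1.77 in palbociclib 1), but both lists were written with KRT5 and KRT14 among their members. Of 20 alternatives 11 ended the epithelial call. Genes of cholesterol biosynthesis (21 of 25, adjusted p = 0.00802; 0.654), the ATF4 response (18 of 23, adjusted p = 0.00973; 0.244) and immediate early genes (15 of 18, adjusted p = 0.0401; 0.747) were lower, the second p of each with an estimated correlation. SLC7A1, an arginine transporter gene, fell when adjusted over the ATF4 list alone (17.2 ± 3.82 against 40.4 ± 11.5). In OPG-Fc against vehicle NF-kB target genes (22 of 29, adjusted p = 2.74e-04; 0.698) were higher. In combination against vehicle the CDK4/6-RB axis (12 of 18, adjusted p = 0.00308; 0.621) and hypoxia genes (20 of 29, adjusted p = 0.0400; 0.746) were lower, and interferon-stimulated genes (25 of 36, adjusted p = 0.00347; 0.677) and ribosomal proteins (27 of 33, adjusted p = 0.0111; 0.746) higher. In combination against palbociclib ribosomal proteins were lower (29 of 33, adjusted p = 5.11e-06, and 0.641 with an estimated correlation). That call ended under quantile normalisation (adjusted p = 0.417). The RANK-RANKL-OPG-TRAIL axis was higher (12 of 15, adjusted p = 0.0410, and 0.641 with an estimated correlation), but 11 of 20 alternatives ended this call. Its 15 tested genes included neither the RANKL gene TNFSF11 nor the RANK gene TNFRSF11A. The latter averaged 0.157 in combination and 0.285 in palbociclib tumours, too low for testing. In combination against OPG-Fc hypoxia genes (17 of 29, adjusted p = 0.0230; 0.728) and mitosis genes (26 of 40, adjusted p = 0.00105; 0.671) were lower, the median of the last turning from -0.11 to 0.02 after rescaling to a common total, as that of all genes moved from 0.10 to 0.23.

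Many of these calls ended on leaving out 1 library, here with the adjusted p. In palbociclib against vehicle these were interferon-stimulated genes (without vehicle 3 0.137, palbociclib 2 0.252), epithelial genes (vehicle 3 0.0987, palbociclib 2 0.527), cholesterol biosynthesis (palbociclib 2 0.442), the ATF4 response (palbociclib 1 0.131) and immediate early genes (vehicle 1 0.205, vehicle 2 0.266, palbociclib 1 0.0941, palbociclib 2 0.0724). In OPG-Fc against vehicle they were NF-kB target genes (vehicle 3 0.315, OPG-Fc 2 0.274). In combination against vehicle they were the CDK4/6-RB axis (combination 2 0.0501), hypoxia (vehicle 1 0.514, vehicle 2 0.919, combination 2 0.485, combination 3 0.781), interferon-stimulated genes (vehicle 3 0.204, combination 1 0.375) and ribosomal proteins (vehicle 2 0.429, vehicle 3 0.562, combination 2 0.749, combination 3 0.154). In combination against palbociclib they were the RANK axis (palbociclib 2 0.412, combination 1 0.0934, combination 2 0.150). In combination against OPG-Fc they were hypoxia (OPG-Fc 2 0.753, combination 2 0.209, combination 3 0.303) and mitosis genes (OPG-Fc 1 0.0637).

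A muscle and a skin gene varied widely between tumours of a group. ACTA1, the skeletal muscle actin gene, lay between 1.45 in palbociclib 1 and 218 in OPG-Fc 1, and KRT14 between 0.130 in OPG-Fc 1 and 172 in palbociclib 2, with 44.0 in combination 2 and 84.8 in combination 3. The 7 lists called in no comparison were the lysosome, the unfolded protein response, senescence and secretory genes, and the adipocyte, keratinocyte, lymphocyte and macrophage markers (lowest adjusted p = 0.0650).

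The other tested genes of MHC class II presentation had interactions of the same sign as CD74, and none passed. HLA-DMA averaged 3.08 ± 0.572 (n = 3) in vehicle, 5.30 ± 3.39 (n = 2) in OPG-Fc, 5.93 ± 0.976 (n = 2) in palbociclib and 2.77 ± 1.43 (n = 3) in combination tumours. HLA-DRA was listed at 0 in 1 combination tumour and lay between 5.68 and 11.8 in the 4 tumours given 1 agent. Of 12 class II genes 5, CD74 included, were tested, all 5 had a negative interaction (median -1.96 log2), and 0 passed. CD74 had been picked for its interaction. HLA-DMB reached 1 FPKM only in tumours given 1 agent (highest 0.87 in vehicle and 0.78 in combination), so the filter favoured its sign. The shared sign is therefore not independent support.

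The hypothesis that palbociclib lowered DNA replication genes with or without OPG-Fc was tested on 5 tumours given palbociclib and 5 others. The E2F list had a mean lower by 0.52 log2 (-0.52; exact two-sided permutation p = 0.0238, adjusted over 25 lists 0.198), which may reflect palbociclib but did not pass the adjustment. It did not lead: the ATF4 response (-0.18) and endothelial markers (-0.44) had an exact two-sided permutation p = 0.0159 each, also 0.198 when adjusted. Over all genes limma called 0 (1125 at an unadjusted p under 0.05; smallest adjusted p = 0.0569). The leading genes, which did not pass, included CCNE1 at 1.77 ± 0.850 against 5.80 ± 0.807, CDC25A at 1.48 against 3.75 and CDC6 at 5.58 against 14.7 (n = 5 and 5). Since the count was 0, all 100 of the 100 splits drawn from 126 had to give as many, which says nothing about chance; 1 split called 1889. That split points to a structure of the samples: its sides were the 5 libraries with a positive GC trend (mean rho 0.218) and the 5 with a negative one (mean rho -0.226). For OPG-Fc, 5 against 5, limma also called 0 genes (278 at an unadjusted p under 0.05), so that again 100 of 100 splits gave as many by necessity (highest 7), and mitosis and G2/M genes were lower by 0.28 log2 (-0.28; exact two-sided permutation p = 0.0317, adjusted over 25 lists 0.794).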
